A study of Arabidopsis thaliana with 4 samples.

How the data were processed

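Leaves of Arabidopsis Ler-0 wild type and *gi* plants were sampled with watering or after drought, giving 4 libraries, 1 per group. Per the labels, plants grew at 23 to 25 °C, 40 to 60% relative humidity and 16 h light and 8 h dark, plants aged 10 d went without water for 10 d, mRNA was purified from 6 µg of total RNA with oligo(dT) beads, and cDNA synthesis was primed with oligo(dT). The labels do not give the *gi* allele, the enzyme that releases the tags, the age or watering of the controls at harvest, the time of day of harvest, or how many plants each library holds. Each file lists 21-base tags that all start with CATG. The deposited count of each tag is its raw copy number, a whole number of at least 2, so tags seen once had been left out before deposit. The deposited TPM of each tag is, per the file headers, transcripts scaled to a fixed library total, and every TPM equalled the copy number divided by the summed copy numbers of its file, times 1000000, to within rounding. The submitters' processing notes name the TAIR10 build and do not state the tag filtering or the mapping software.

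Tags were matched anew to the TAIR10.1 genome and its annotation, on which all coordinates are given. Every 21-base sequence that starts at a CATG site of an annotated transcript, in the sense direction, was listed, and a tag was assigned to a gene if it matched the transcripts of that gene only, without mismatch. The copies of all such tags of a gene were summed. Of 38312 annotated genes 33271 could yield such a tag. Across the libraries 210702 different tags were listed. Tags matching several genes (4.92%, 2.08%, 2.68% and 2.52% of copies in the wild type control, wild type drought, *gi* control and *gi* drought libraries), antisense matches only (7.87%, 8.38%, 8.69% and 8.96%), the genome only (2.56%, 3.89%, 4.69% and 5.42%) or nothing (7.89%, 13.9%, 16.2% and 10.9%) were left out of gene counts but kept in the library totals. Of the assigned copies 68.8%, 73.7%, 71.0% and 72.9% came from the most 3' site of a transcript.

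Levels are gene copies divided by the library total, in TPM. Log2 ratios used a pseudocount of 1 TPM. The ratio of 2 counts, scaled by the totals, carries an exact (Clopper-Pearson, conditional binomial) 95% interval, and a level an exact Poisson interval. Both cover counting error only: with 1 library per group no spread between plants could be estimated, so no test was made and no p-value is given. A gene was called at a log2 ratio of at least 1 in size (2-fold), a level of at least 30 TPM in the higher library and an interval that excluded 1. Folds are ratios of scaled counts without a pseudocount. Where a gene was not listed in one library, the fold was computed against a floor of 3 copies in that library and is given as "at least". It is a bound at that floor and not a 95% limit. Comparisons were drought against control in each genotype and *gi* against wild type in each condition. The difference of the drought log2 ratios (*gi* minus wild type) was counted where it was at least 1 and above 2 counting standard errors, with at least 30 TPM in any library. Correlations across genes used the same level.

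The 24 gene lists, of 379 entries, were written before the data were examined, as were the rules above, the first group of alternatives below and the rule for naming genes. Entries were matched by locus code, or by symbol where code and symbol disagreed. 1 entry was dropped because it could not be matched, and 35 of the other 378 had no unambiguous tag listed in any library, including 13 that cannot yield one. List members needed 5 TPM in the higher library. A list's median was given for at least 3 members, with its percentile among 10000 random lists of equal size matched on expression, which describes these libraries and is not a test. Members are counted as higher or lower at 2-fold with an interval that excluded 1. Genes were named by rule: *GI*, *CO*, *FT*, *FKF1*, *CCA1*, *LHY*, *TOC1*, *RD29A*, *RD29B*, *RAB18*, *NCED3*, *P5CS1* and *WRKY44* always, the 6 highest and 6 lowest called log2 ratios of each comparison, up to 2 members with the highest and 2 with the lowest log2 ratio per list, and the 5 highest and 5 lowest differences.

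The tag-end adjustment was chosen after the data had been seen. For each library, the log2 level of each tag with at least 200 copies in all, minus its mean over the 4 libraries, was taken, and its median was computed for each of the 64 combinations of the tag's last 2 bases and the transcript base at position 22. Classes of fewer than 10 tags used the factor of the last 2 bases. Tag levels were divided by these factors before being summed per gene. The largest factors differed 18.4-fold between libraries (AAA) and the smallest 1.13-fold (GGT). The last 2 bases with the next base accounted for 78.2% of the variance of the contrast between the drought responses.

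Alternatives fixed in advance were TMM factors (edgeR 4.0.16), DESeq2 1.42.0 size factors, upper-quartile scaling, totals without organelle genes and the 20 most abundant nuclear genes, pseudocounts of 0.1 and 5, no minimum level or 10 TPM, 1.5-fold and 4-fold thresholds, tags of the most 3' site only, tags with 1 mismatch accepted (13282 tags, since Ler differs from the reference strain), and shared tags counted for each gene. The tag-end adjustment, leaving out tags that end in AA or TT, and setting tags of 2 copies to 0 were added after the data had been seen. Computations used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9, and R 4.3.3.

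The calling rules were tested on simulated counts at the depths of the libraries, with 200 changed genes in each comparison. At 2-fold, on the threshold itself, 38% to 58% of 50 changed genes were called in the 4 comparisons, and at 3-, 4- and 8-fold 100%. No unchanged gene was called among 4501, 4378, 4049 and 4621, and 94.9% to 95.3% of the intervals held the true ratio. For the difference, 48% were called at 2-fold and 2 of 4710 unchanged genes. Up to here only the changed genes and counting noise set the simulated libraries apart. Few calls of unchanged genes were thus built in, and the rates cover counting error only, not differences between plants or libraries. With tag-end factors simulated as well, 3905 of 7300 unchanged genes were called different without the adjustment and 16 of 4788 with it. In that simulation all tags of an end class shared 1 exact factor per library. Apart from the 200 changed genes, only these factors and counting noise set the libraries apart. The simulation therefore does not give the rate of false calls after adjustment in the real libraries. Changed genes were called in 38% (without) and 16% (with) of cases at 2-fold, 56% and 98% at 3-fold, 68% and 100% at 4-fold, and 86% and 100% at 8-fold. At the depths of the libraries 30 TPM is 102, 110, 111 and 103 copies, with Poisson limits between 24.4 and 36.4 TPM, and the upper limit for a count of 0 is 1.08, 1.0, 1.0 and 1.07 TPM, in the order above. Because tags seen once had been left out, a gene not listed need not have had 0 copies.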

Results

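Gene expression was compared in leaves of *Arabidopsis thaliana*, in the Ler-0 (Landsberg erecta) wild type and in a *gi* mutant of the same background, with and without drought. *GIGANTEA* (*GI*) encodes a nuclear protein of the circadian clock that is needed for flowering in long days. The labels do not name the mutant allele. Drought meant that plants aged 10 d were left without water for 10 d. The assay was digital gene expression, in which each mRNA is represented by a short tag, here of 21 bases, that starts at a CATG site, and the copies of each tag are counted. Each of the 4 groups was a single library. The libraries held 3402732 tag copies in the wild type control, 3680315 in the wild type drought library, 3689354 in the *gi* control and 3447986 in the *gi* drought library. Tags that matched 1 gene only, in the sense direction, made up 76.8%, 71.8%, 67.7% and 72.2% of these copies in the same order, and 22186 genes had at least 1 such tag. With 1 library per group there was no replicate check, so each comparison is of libraries and not of conditions, and the 95% intervals below cover counting error only. A gene is called higher or lower when it differed at least 2-fold, had a level of at least 30 TPM (tag copies scaled to a library total of 1000000) in the higher library and had an interval that excluded 1.

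The libraries differed in which tag ends they held, whatever the gene. Tags ending in TT made up 18.9% of copies in the wild type control and 14.3% in the *gi* drought library, but 4.56% in the wild type drought library and 2.18% in the *gi* control. Tags ending in AA ran the other way, with 4.56% and 9.54% in the first pair and 17.9% and 24.5% in the second. These shares cover all tags, also those that match no gene. Unmatched tags ending in a run of A made up 0.0542% and 0.799% of copies in the first pair and 3.64% and 5.11% in the second. The last 2 bases of a tag accounted for 61.9% of the variance, over 8003 tags, of the log2 drought ratio in *gi* minus that in the wild type, and any pair of adjacent bases from position 5 to position 19 accounted for at most 1.3%. Values were therefore also computed after each library's levels were divided by the median factor of the tag end, a step chosen after the data had been seen. Such adjusted values are given beside a result where the adjustment ended a call, turned a direction or moved a value by more than 1.5-fold, and for counts of list members where the counts changed. Their intervals leave out the uncertainty of the factors themselves.

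**Figure D1:**
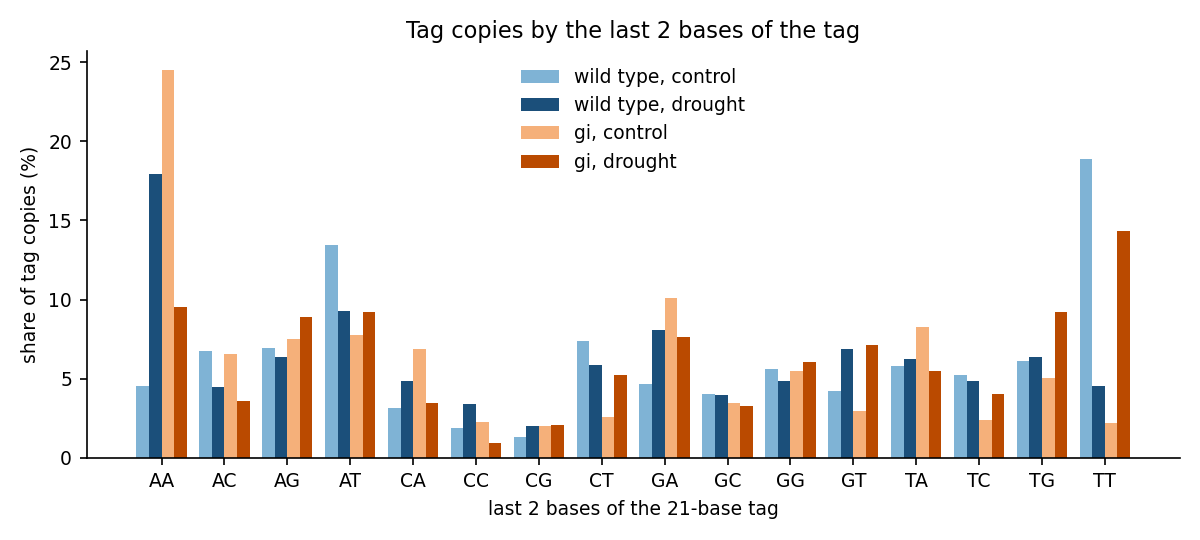
Share of tag copies, in percent, by the last 2 bases of the tag in each of the 4 libraries, over all tags including those that match no gene. TT was at 18.9% in the wild type control and 2.18% in the *gi* control, and AA was at 4.56% and 24.5%.

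*GI* (AT1G22770) lies on chromosome 1 at positions 8061751 to 8067790 on the forward strand of the TAIR10.1 reference, and 97.6% of its copies came from a tag in a coding exon at 8067213 to 8067233. Its level was 48.2 TPM in the wild type control (95% Poisson interval 41.1 to 56.2) and 42.8 in the *gi* control (36.4 to 50.05), a ratio whose interval, 0.899 to 1.41-fold lower in *gi*, included 1. In the wild type drought library *GI* stood at 119.6 TPM, 2.48-fold above its control (2.07 to 2.99), and in the *gi* drought library at 25.5. After adjustment the wild type drought ratio was 1.28-fold higher and no longer called. Transcripts of the mutated gene were thus counted in both *gi* libraries, and a tag near the 3' end need not be affected by a mutation elsewhere in the gene.

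The first comparison asked which genes differed between watered and droughted leaves of the wild type. Many genes of the dehydration response stood far higher in the droughted library: *RAB18*, a dehydrin gene, was 319-fold higher (259 to 397), *LEA7*, a late embryogenesis abundant gene, 260-fold (119 to 709), and *RD29B* 99.8-fold (54.0 to 209, 212-fold adjusted). Many genes of photosynthesis stood lower, among them *RBCS1A*, which encodes the small subunit of Rubisco and was 20.8-fold lower (20.1 to 21.5). Of 5798 genes at or above the minimum level, 1828 were called higher and 1348 lower. After adjustment 1379 were called higher and 672 lower among 5095 genes, and 929 and 501 of these were also called the same way without it. The split depended on the scaling between libraries: with TMM factors 1454 genes were higher and 1690 lower, and 46.2% of calls were higher against 57.6% with library totals. DESeq2 size factors gave 45.8% and upper-quartile scaling 44.8%. The median log2 ratio of all genes, 0.26 with library totals, shifted by -0.24, -0.25 and -0.27 under these scalings.

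In the wild type, 22 of the 29 measured dehydration-responsive genes were higher and 2 lower (23 and none adjusted), with a median log2 ratio of 3.13 that lay above all 10000 random lists of matched expression. *RAB18* (AT5G66400, chromosome 5, 26518277 to 26519447) went from 26.2 to 8334 TPM, its main tag lying in the 3' UTR. *LTP3*, for a lipid transfer protein, was 601-fold higher (370 to 1052, 112-fold adjusted). *RD29A* was 1.26-fold higher (1.17 to 1.36, 2.40-fold adjusted). *RD19* was 2.69-fold lower (1.58-fold adjusted) and *GolS1* 2.38-fold lower, and neither was called after adjustment, when *GolS1* was 1.70-fold higher. *P5CS1*, for a proline synthesis enzyme, was 9.17-fold higher (8.18 to 10.3). Of the genes with the highest ratios, AT2G37870 was 620-fold higher (242 to 2278, 383-fold adjusted), AT3G53980 199-fold (131 to 318, 47.9-fold adjusted), and AT3G17520, unlisted in the control, at least 254-fold.

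Of 28 measured genes of abscisic acid (ABA) metabolism and signalling, 21 were higher and 2 lower (18 and 2 adjusted), with a median of 1.75 that was also above all random lists. *NCED3*, which encodes a rate-limiting enzyme of ABA synthesis, was 8.57-fold higher (6.48 to 11.5). The protein phosphatase genes *HAI1* and *ABI2* were 51.8-fold (37.1 to 74.6) and 19.9-fold higher (14.8 to 27.4). *PYL8*, for an ABA receptor, was 6.52-fold lower (5.32 to 8.05). In the flavonoid and anthocyanin list 12 of 16 measured members were higher and none lower, with a median of 2.89. *DFR*, for dihydroflavonol reductase, was 54.7-fold higher (36.0 to 87.6, 29.5-fold adjusted), and *F3H*, unlisted in the control, was at least 76.4-fold higher with a log2 ratio of 6.10 (5.11 adjusted). All 4 measured heat shock genes were higher, including *HSP70-4* at 5.60-fold (3.96 to 8.11). In the leaf senescence list 7 of 10 members were higher and 1 lower, with a median of 1.81 at percentile 99.7 of the random lists. *NYE1*, a chlorophyll degradation gene, was 16.1-fold higher (8.77 to 32.7, 4.24-fold adjusted), *SAG12* was at least 12.0-fold higher without reaching the minimum level, and *PAO* was 2.82-fold lower before adjustment and 1.61-fold higher after it.

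Of 28 measured genes of the photosystems and their light-harvesting antennae, 20 were lower and 2 higher in the droughted wild type (20 and none adjusted), with a median of -2.31 (-1.29 adjusted) below all random lists. *LHCB1.4*, for a chlorophyll-binding antenna protein, was 143-fold lower (113 to 182, 60.0-fold adjusted), and *PSBQ-1* was 26.6-fold lower (14.99 to 52.05, 12.0-fold adjusted). *LHCA1* was 2.28-fold higher, and after adjustment 1.16-fold lower. In the Calvin cycle list 10 of 15 members were lower and none higher, with a median of -1.66, and after adjustment 10 were lower and 2 higher (*GAPA* and *FBA2*, which lie outside the naming rule and were looked up after the counts had been seen), with a median of -1.13. *RBCS1A* (AT1G67090, chromosome 1, 25048158 to 25049667) alone went from 75695 to 3938 copies, and *RBCS1B* was 30.7-fold lower (15.3 to 72.0). Aquaporins, the water channel genes, were lower in 9 of 13 measured members and higher in 2, with a median of -1.90, but after adjustment lower in 4 and higher in 1, with a median of -0.74. *TIP1;2* was 35.8-fold lower (29.3 to 44.0, 6.02-fold adjusted) and *PIP2;6* 12.5-fold lower (10.7 to 14.7, 3.10-fold adjusted), while *PIP1;4* was 3.98-fold higher (2.84 to 5.68). Glucosinolate genes were lower in 9 of 14 members and higher in 1 (5 and 1 adjusted), with a median of -1.45 (-0.58 adjusted), *MAM3* being 9.48-fold lower (7.63 to 11.9, 4.95-fold adjusted) and *CYP83B1* 4.78-fold lower (3.92 to 5.88, 2.04-fold adjusted). The germin-like gene *GER1* had the lowest ratio at 230-fold lower (175 to 308, 48.5-fold adjusted). Also among the 6 lowest were AT3G05730 (146-fold), AT3G06070 (152-fold), *FKBP13* (107-fold) and the histone gene AT1G09200 (at least 59.9-fold), which after adjustment stood at 36.8-fold, 26.1-fold, 17.4-fold and, for AT1G09200, below the minimum for a call.

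Other lists were mixed in the wild type. For sugar and starch 11 of 24 members were higher and 7 lower (9 and 7 of 25 adjusted), with a median of 0.90. *SWEET15*, for a sugar exporter, was 275-fold higher (75.8 to 2277, 549-fold adjusted) from 2 copies in the control, *SUS3* was 82.6-fold higher (41.7 to 192, 51.2-fold adjusted), and *SPS4F* was 17.4-fold lower (12.7 to 24.4, 4.37-fold adjusted). The salicylate defence list had 4 of 7 members higher (3 adjusted), with *PR2* 59.4-fold higher (35.8 to 107, 21.1-fold adjusted) and *PR1* at least 56.4-fold higher (log2 5.66, or 4.65 adjusted), below the minimum for a call after adjustment. The jasmonate and wounding list had 3 of 9 members lower and 1 higher (3 and 2 adjusted). Its regulator *MYC2* was 13.96-fold lower (9.04 to 22.6, 6.48-fold adjusted), and *AOC2* was 6.18-fold lower (5.49 to 6.97, 1.52-fold adjusted and not called). In the reactive oxygen list 4 of 7 members were higher (1 adjusted) and *CSD2* was 5.11-fold lower (4.63 to 5.65). Among 6 cell wall loosening genes 3 were lower, *EXPA8* by 74.6-fold (20.3 to 622, 49.98-fold adjusted and not called), and 1 was higher (2 lower and 1 higher adjusted). Of 12 genes for photoreceptors and light signalling 4 were higher and 3 lower (2 and 1 adjusted). *ELIP1* was 7.17-fold higher (3.91 to 14.4, 31.1-fold adjusted).

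The labels do not give the time of day of harvest, on which levels of clock genes depend, so clock values here and below need not reflect drought or genotype. Clock genes were more often higher than lower in the droughted wild type, 9 against 4 of 18 (7 against 1 of 17 adjusted), with a median of 1.13 at percentile 98.4. *CCA1* went from 3 to 65 copies, 20.03-fold higher (6.56 to 99.7), and *RVE4* was 11.2-fold higher (6.20 to 22.1, 5.71-fold adjusted). *TOC1* was 3.73-fold lower (3.11 to 4.50, 1.96-fold adjusted and not called), and *PRR7* was 4.36-fold lower before adjustment and 1.23-fold higher after it. *FKF1* was 1.35-fold higher (1.1 to 1.65), and *LHY* had 2 copies in the control and was not listed elsewhere. Flowering genes went both ways, with 5 higher and 4 lower of 15 (3 and 2 of 13 adjusted). *CO*, which activates flowering in long days, was 5.84-fold lower (2.94 to 12.9, 2.64-fold adjusted) and its target *FT* 5.41-fold lower (1.15 to 50.8, 1.25-fold adjusted), both below 30 TPM, whereas *SOC1* was 3.04-fold higher (2.48 to 3.76, 1.02-fold adjusted). *WRKY44* had 8 copies in the control and was not listed after drought, at least 2.88-fold lower (log2 -1.74, or -0.85 adjusted). *CBF3* was 3.65-fold higher (2.53 to 5.39). Few markers of other organs were measured. Of the 8 root, 8 flower and 8 seed markers, 8, 8 and 7 could yield an unambiguous tag, 7, 7 and 2 had one listed in any library, and 2 root markers, no flower marker and no seed marker reached 5 TPM in this comparison. *BGLU23*, a root marker, was 2.99-fold higher (2.65 to 3.39, 1.3-fold adjusted). Among 3 measured guard cell genes *SLAC1* was 12.4-fold lower (4.54 to 47.6, 5.44-fold adjusted) and *FAMA* 4.45-fold lower (2.63 to 7.91). Of 7 reference genes 2 were lower (none adjusted): *ACT8* was 4.70-fold lower (3.91 to 5.69, 1.13-fold adjusted) and *UBQ10* 2.42-fold lower (2.3 to 2.55), which became 1.96-fold higher after adjustment.

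**Figure D2:**
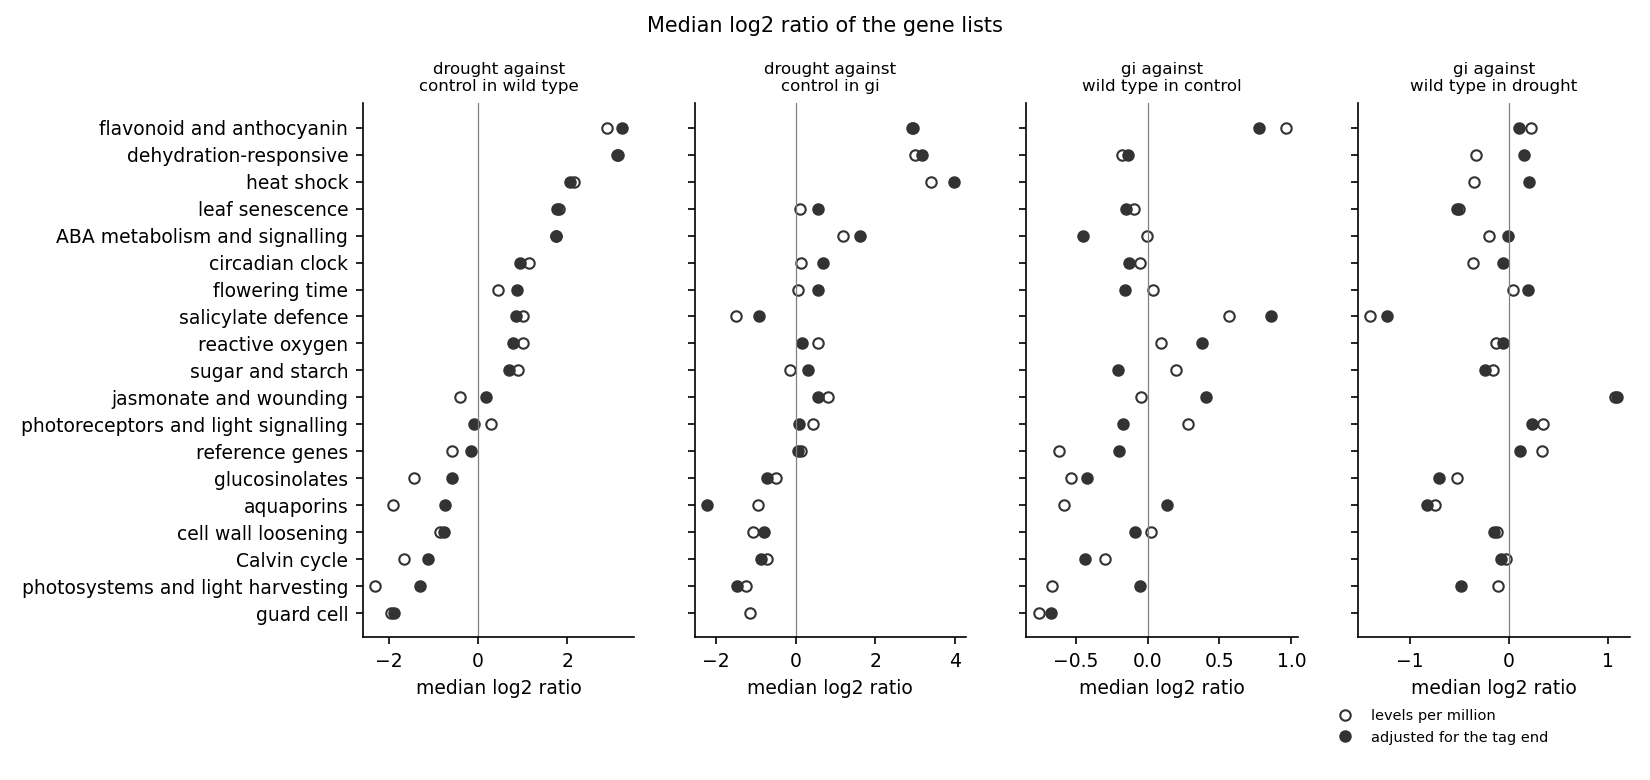
Median log2 ratio of the gene lists in the comparisons, without and with the tag-end adjustment. The dehydration-responsive list stood at 3.13 in the wild type and 2.99 in *gi* after drought, and the photosystem list at -2.31 and -1.25.

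The same question was asked of *gi* leaves. Many dehydration and ABA genes stood high in the droughted *gi* library: *RAB18* was 410-fold higher (316 to 541), *RD29B* 124-fold (62.5 to 287), *NCED3* 8.88-fold (6.46 to 12.5) and *P5CS1* 10.5-fold (9.74 to 11.3). *RBCS1B*, for a Rubisco small subunit, was 39.7-fold lower (19.9 to 92.8) and the aquaporin gene *TIP2;1* 45.5-fold lower (34.3 to 61.7, 25.3-fold adjusted). Of 5661 genes at the minimum level, 1854 were called higher and 1379 lower. After adjustment the counts were 1549 and 745 of 5038, with 1063 and 572 shared. Higher calls made up 57.3% with library totals and 46.8% with upper-quartile scaling, under which 1546 genes were higher and 1757 lower. With DESeq2 size factors these were 1621 and 1674, and with TMM factors 1705 and 1579. The median log2 ratio of all genes, 0.19, shifted by -0.12 with TMM, -0.17 with DESeq2 and -0.23 with upper-quartile scaling.

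Of the 29 measured dehydration-responsive genes, 20 were higher and 1 lower in droughted *gi* (22 and 1 adjusted), with a median of 2.99, again above all random lists. *LTP3* was 272-fold higher (167 to 477, 1158-fold adjusted). *COR15B*, for a cold-regulated chloroplast protein, was the one that was lower, by 47.9-fold (37.7 to 61.8, 23.2-fold adjusted). *RD29A* was 1.17-fold lower (1.06 to 1.29) before adjustment and 1.65-fold higher after it. In the ABA list 16 of 28 members were higher and 5 lower (18 and 3 of 27 adjusted), with a median of 1.2, and *HAI2* and *HAI1* were 100.3-fold (38.9 to 370) and 51.6-fold higher (40.3 to 67.0, 30.7-fold adjusted). The flavonoid list had 12 of 18 members higher and 2 lower (11 and none of 15 adjusted), with a median of 2.94. Its *GSTF12*, needed for anthocyanin transport, was 162-fold higher (44.5 to 1345, 20.3-fold adjusted) and *DFR* 36.3-fold higher (27.2 to 49.4, 14.9-fold adjusted). All 3 measured heat shock genes were higher, *HSP70-4* by 11.8-fold (8.09 to 18.0, 18.7-fold adjusted). The highest ratios belonged to AT3G56275, which has no annotated product, at least 723-fold, *SWEET15* at least 523-fold, AT5G50360 at least 449.8-fold (log2 8.52, or 7.31 adjusted), AT3G17520 at least 393-fold and AT2G41190 at 779-fold (215 to 6438, 309-fold adjusted).

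In the photosystem list 16 of 28 members were lower and 4 higher in droughted *gi* (19 and 1 adjusted), with a median of -1.25. *PSBO2* was 14.8-fold lower (13.3 to 16.5, 5.96-fold adjusted) and *LHCB4.3* 24.8-fold lower (15.1 to 43.7, 6.78-fold adjusted). *LHCB1.3* was 11.4-fold higher (10.9 to 12.0, 2.97-fold adjusted), and *LHCA2* was 8.52-fold higher before adjustment and 1.12-fold lower after it. In the Calvin cycle list 7 of 15 members were lower and 2 higher (7 and none adjusted), with a median of -0.73, *RCA* being 5.42-fold lower (5.26 to 5.58). Aquaporins were lower in 6 of 12 and higher in 2, with a median of -0.95 (-2.23 adjusted, 8 of 13 lower and none higher), and *PIP1;5* was 6.37-fold lower (5.16 to 7.93). Of 14 glucosinolate genes 6 were lower and 2 higher (5 and none adjusted), and *CYP83A1* was 7.55-fold lower (6.36 to 9.02, 2.89-fold adjusted). Of 6 cell wall loosening genes 3 were lower and 1 higher (3 and none adjusted), *EXPA8* being 17.8-fold lower (4.59 to 152) below the minimum level. The 6 lowest ratios were those of AT2G10940 (182-fold lower, 133 to 255, 121-fold adjusted), *XTH6*, for a cell wall remodelling enzyme (105-fold, 40.8 to 388), *BZIP61* (148-fold, 40.7 to 1228, 79.7-fold adjusted), and the unlisted AT1G04800, AT5G19190 and AT1G11850, at least 132-fold, 83.5-fold and 58.6-fold lower. The log2 ratios of AT1G04800 and AT5G19190 were -6.86 and -6.20 before and -6.19 and -5.45 after adjustment, and AT1G11850, at -5.70 before and -4.92 after, was then not called.

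In the salicylate list 4 of 7 members were lower in droughted *gi* and none higher (3 and 1 of 6 adjusted), with a median of -1.5 (-0.93 adjusted). *ICS1*, for the salicylate synthesis enzyme, was 4.36-fold lower (2.31 to 8.94), and *PR1* was 16.8-fold lower (5.46 to 84.1, 4.96-fold adjusted) with 54 and 3 copies. The jasmonate list had 4 of 11 members higher and 2 lower (5 and 2 adjusted), and *CORI3* was 74.5-fold higher (58.6 to 96.3, 10.7-fold adjusted). The sugar and starch list had 8 of 25 members higher and 9 lower, but 8 of 24 higher and 1 lower after adjustment, and *APL3*, for a starch synthesis enzyme, was 53.6-fold higher (39.3 to 74.9). In the senescence list 4 of 9 members were higher and 1 lower (4 and none adjusted). Its median was 0.11 with library totals and -0.12 with upper-quartile scaling, and *SAG21* was 79.4-fold higher (67.3 to 94.3, 19.7-fold adjusted). Of 12 photoreceptor and light signalling genes 4 were higher and 2 lower (2 and none of 11 adjusted), and *ELIP1* was 612-fold higher (169 to 5060, 58.3-fold adjusted) from 2 copies. In the reactive oxygen list 3 of 7 members were higher and 2 lower (1 and 1 adjusted), *CSD2* being 4.74-fold lower (4.3 to 5.24, 2.99-fold adjusted). Among 3 guard cell genes 2 were lower, but none of 2 after adjustment. Of the other-organ markers, *BGLU23* was 7.24-fold lower (5.63 to 9.42, 3.4-fold adjusted), *SHP1*, a flower marker, had 3 and 29 copies, and no seed marker reached 5 TPM. *UBQ10* was 25.7-fold higher (22.7 to 29.2, 3.21-fold adjusted), and *ACT8* was 7.92-fold higher before adjustment and 1.08-fold lower after it.

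Of 18 clock genes 7 were higher and 3 lower in droughted *gi* (6 and 2 adjusted), and their median was 0.13 with library totals and -0.08 with upper-quartile scaling. *LNK1* was 41.3-fold higher (24.8 to 74.3, 9.91-fold adjusted), *FKF1* 2.25-fold higher (1.78 to 2.84), *CCA1* at least 8.56-fold higher with 24 copies against none listed, and *TOC1* 1.28-fold lower (1.05 to 1.57). *GI* itself was 1.68-fold lower (1.28 to 2.2) and, after adjustment, 1.34-fold higher. In the flowering list 5 of 14 members were higher and 2 lower (6 and 1 adjusted), with a median of 0.05 that was -0.18 with upper-quartile scaling. *SPL4* was 49.6-fold higher (16.6 to 243) from 3 copies, *TEM2* 8.35-fold lower (5.71 to 12.6, 5.38-fold adjusted), and *SOC1* 2.49-fold lower, or 1.37-fold higher after adjustment. *CO* had 5 copies in the control and was not listed after drought, at least 1.56-fold lower, and *FT* and *LHY* were listed in neither *gi* library. *WRKY44* had 22 copies after drought and none listed in the control, at least 7.85-fold higher (log2 2.88, or 1.90 adjusted). Of the CBF cold regulators, which had 2 measured members, none was higher and 1 was lower.

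Wild type and *gi* controls were compared to ask what differed between the genotypes with water. *CO* was 11.7-fold lower in *gi* (4.72 to 37.5), with 54 against 5 copies, and *FT* was listed in the wild type only, with 10 copies, at least 3.61-fold lower in *gi* (log2 -1.98, or -1.0 adjusted). Both stayed under 30 TPM, so neither was called. *P5CS1* was 2.23-fold higher in *gi* (1.96 to 2.55), *COR15B* 30.9-fold higher (25.4 to 37.9, 9.28-fold adjusted), and *RBCS1A* 7.74-fold lower (7.58 to 7.90). Of 5229 genes 1200 were called higher and 1312 lower, and after adjustment 427 and 567 of 4219, of which 304 and 348 were shared with the first set. More genes were lower than higher also with TMM factors (1435 and 1220), DESeq2 size factors (1354 and 1308), totals without organelle and top genes (1416 and 1150) and at 4-fold (754 and 597), but not with upper-quartile scaling (1336 and 1339) or without tags ending in AA or TT (700 and 737). This comparison set the library richest in tags ending in TT against the one richest in AA.

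In the control comparison the flavonoid list had 6 of 12 members higher in *gi* and none lower (5 and none of 10 adjusted), with a median of 0.96 at percentile 98.9 (0.77 adjusted, at 99.9). *F3H* was at least 9.53-fold higher (log2 3.23, or 1.89 adjusted), while *PAL1* was 4.54-fold higher before adjustment and 1.77-fold lower after it. The salicylate list had 3 of 7 members higher and none lower (3 and none of 6 adjusted), with *PR2* 10.5-fold higher (6.20 to 19.2, 3.24-fold adjusted and not called) and *PR1* at least 16.6-fold higher (log2 3.97, or 2.52 adjusted). The photosystem list had 13 of 28 members lower and 3 higher with a median of -0.67, but after adjustment 6 were lower and 1 higher with a median of -0.05. *LHCB1.3* was 29.0-fold lower (27.6 to 30.4, 4.45-fold adjusted). *BGLU18*, which releases ABA from a stored conjugate, was 7.53-fold higher (6.74 to 8.42, 4.42-fold adjusted). Among jasmonate genes 3 of 11 were higher and 4 lower (2 and 2 adjusted), *MYC2* by 6.04-fold (4.47 to 8.30, 3.97-fold adjusted) and *AOC2* by 8.57-fold (7.48 to 9.84, 2.53-fold adjusted), and *AOS* was 5.67-fold higher (4.94 to 6.52, 1.66-fold adjusted and not called). *MAM3* was 5.90-fold lower (4.95 to 7.08, 2.64-fold adjusted), *FAMA* 6.17-fold lower (3.4 to 12.1), *PIF5* 2.77-fold higher (2.24 to 3.46), and *TIP1;2* 7.60-fold lower (6.91 to 8.39, 1.01-fold higher adjusted). Of the other-organ markers only 2 root markers reached 5 TPM in the control comparison: *TIP2;3* was 9.76-fold lower in *gi* (2.34 to 86.7, 3.89-fold adjusted with an interval that included 1), with 18 and 2 copies, and *BGLU23* was 1.46-fold higher before and 2.35-fold lower after adjustment.

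Clock and flowering genes differed in both directions in the control comparison, with 5 of 16 clock genes higher and 6 lower (4 and 3 adjusted) and 3 of 14 flowering genes higher and 4 lower (3 and 4 of 13 adjusted). *TOC1* was 2.44-fold lower in *gi* (2.09 to 2.86, 1.71-fold adjusted and not called), *LNK1* 11.3-fold lower (6.63 to 20.6, 1.94-fold adjusted and not called), *FKF1* 1.61-fold lower (1.26 to 2.07), and *RVE8* 14.8-fold higher (4.76 to 74.1) with 3 and 48 copies. *PRR7* was 5.38-fold lower before adjustment and 1.23-fold higher after it. *CCA1* had 3 copies in the wild type and was not listed in *gi*. *SPL3* was 3.67-fold higher (2.85 to 4.76), *TEM2* 4.75-fold higher (3.52 to 6.53, 2.13-fold adjusted), and *SPL4* 15.9-fold lower (5.10 to 80.1) with 44 and 3 copies. *WRKY44* was listed in the wild type only, with 8 copies, at least 2.89-fold lower in *gi* (log2 -1.74, or -0.85 adjusted). *RD29A* was 1.3-fold lower (1.2 to 1.42), *RD29B* 1.36-fold lower (0.482 to 3.95), *NCED3* 1.39-fold lower (0.914 to 2.12, 2.18-fold adjusted), and *RAB18* 1.69-fold lower (1.2 to 2.40) before and 1.36-fold higher after adjustment. *UBQ10* and *ACT8* were 19.8-fold (17.4 to 22.5) and 10.6-fold lower (8.13 to 13.9), against 1.83-fold lower and 1.03-fold higher after adjustment.

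The genes with the largest ratios between the controls kept less of them after adjustment. *ZFN1*, *SAR1B*, *HSBP*, *MKK2* and AT3G28900 were 72.9-fold, 64.2-fold, 54.3-fold, 69.9-fold and 55.6-fold higher in *gi*, and 4.89-fold, 6.27-fold, 2.99-fold, 3.80-fold and 3.02-fold higher after adjustment. *ABCB26*, unlisted in the wild type control, was at least 82.4-fold higher. AT3G06750, AT2G23090, *GER1* and *CIPK21* were 169-fold, 88.8-fold, 62.0-fold and 48.4-fold lower, and 20.8-fold, 8.22-fold, 5.74-fold and 20.8-fold lower after adjustment. *STP4* and *MGT4* were not listed in *gi*, at least 66.9-fold and 47.0-fold lower. *ABCB26*, *STP4* and *MGT4* were not called after adjustment, when their log2 ratios went from 6.20, -5.79 and -5.29 to 4.61, -4.24 and -3.81.

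Droughted *gi* was compared with droughted wild type to ask how the genotypes differed without water. In the jasmonate list 5 of 9 members were higher in *gi* and none lower, with a median of 1.07 at percentile 99.7. In the salicylate list 3 of 6 members were lower and none higher, with a median of -1.40 at percentile 0.18. *PR1*, the marker of salicylate defence, was 57.2-fold lower in *gi* (19.2 to 280, 25.2-fold adjusted and not called), with 183 against 3 copies, and *MYC2* was 6.6-fold higher (4.19 to 10.9). Of 5548 genes 755 were called higher and 941 lower, the lowest share of genes called in the 4 comparisons at 30.6%, and after adjustment 292 and 414 of 5078, of which 201 and 291 were shared. Which direction held more genes depended on the scaling and the fold: 818 were higher and 765 lower with TMM factors, 828 and 735 with DESeq2 size factors and 808 and 747 with upper-quartile scaling, and 208 and 192 at 4-fold, but 316 and 731 without tags ending in AA or TT. The median log2 ratio of all genes was -0.08 and shifted by 0.11 with DESeq2 size factors.

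Among the other genes of that comparison, *CORI3* was 7.88-fold higher in *gi* (7.25 to 8.58, 2.28-fold adjusted) and *PAD4* 7.50-fold lower (3.41 to 19.5, 4.88-fold adjusted) with 56 and 7 copies. Of 29 dehydration-responsive genes 4 were higher and 10 lower, and after adjustment 2 were higher and 2 lower. *P5CS1* was 2.55-fold higher (2.45 to 2.66), *DREB2A* 5.26-fold higher (3.43 to 8.35, 3.87-fold adjusted and not called), *COR15B* 8.36-fold lower (6.50 to 10.9, 4.89-fold adjusted), *RD29A* 1.92-fold lower (1.76 to 2.1), *RD29B* 1.09-fold lower (1.0 to 1.19), *NCED3* 1.34-fold lower (1.17 to 1.54), and *RAB18* 1.32-fold lower (1.29 to 1.34) before and 1.43-fold higher after adjustment. In the ABA list 1 of 27 members was higher, *ABF3* by 2.53-fold (2.3 to 2.79), and 6 were lower (1 and 3 adjusted). *CBF3* was 6.84-fold lower (4.27 to 11.5). Aquaporins had a median of -0.74 at percentile 1.87, with *PIP1;4* 4.68-fold lower (3.28 to 6.86, 3.06-fold adjusted) and *PIP2;6* 5.91-fold higher (5.02 to 6.98, 2.72-fold adjusted). The photosystem list had 6 of 27 members higher and 9 lower (2 and 8 of 28 adjusted), with *LHCB1.3* 6.63-fold higher (6.37 to 6.89) and *PSBY* 11.8-fold lower (9.74 to 14.5, 3.03-fold adjusted). Its median moved from -0.11 at percentile 38.5 to -0.49 at percentile 0.0400 with adjustment, and that of the glucosinolate list from -0.52 at percentile 5.32 to -0.71 at percentile 0.0900. *CYP79F1* was 2.94-fold lower (2.45 to 3.55). In the Calvin cycle list *PGK1* was 3.51-fold higher (3.37 to 3.65) and *GAPA* 3.75-fold lower (3.34 to 4.21). *ELIP1* was 13.1-fold higher (10.6 to 16.4, 3.81-fold adjusted).

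With drought, *GI* was 4.68-fold lower in *gi* than in the wild type (3.72 to 5.96), but 1.11-fold lower after adjustment and not called. *ELF4*, an evening clock gene, was 3.75-fold lower (3.25 to 4.34, 2.41-fold adjusted), *CCA1* 2.54-fold lower (1.57 to 4.24, 1.62-fold adjusted), *TOC1* 1.19-fold higher (0.954 to 1.5) and *FKF1* 1.04-fold higher (0.862 to 1.25) before and 1.21-fold lower after adjustment. *SOC1* was 3.97-fold lower (3.16 to 5.02, 1.90-fold adjusted and not called). *CO* had 10 copies in the wild type and was not listed in *gi*, at least 3.12-fold lower, *FT* had 2 copies in the wild type only, *LHY* was listed in neither, and *WRKY44* was at least 7.83-fold higher with 22 copies in *gi*. *UBQ10* was 3.15-fold higher (3.0 to 3.31) before and 1.11-fold lower after adjustment, and *ACT8* 3.53-fold higher (2.92 to 4.29, 1.08-fold adjusted and not called).

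At the extremes of the drought comparison, the stress-responsive transcription factor gene *RRTF1* had 107 copies in *gi* and was not listed in the wild type, at least 38.1-fold higher (log2 5.0, or 4.31 adjusted), and AT4G29780 was 34.7-fold higher (15.7 to 95.7, 9.89-fold adjusted); neither was called after adjustment. AT3G51500, *ACX2*, AT5G23460 and AT2G35840 were 16.6-fold, 14.9-fold, 17.3-fold and 13.4-fold higher, and 4.74-fold, 4.70-fold, 4.97-fold and 4.32-fold higher after adjustment. AT1G14240, unlisted in *gi*, was at least 48.1-fold lower. AT4G12770 was 67.5-fold lower (18.3 to 562, 142-fold adjusted), AT4G11320, for a papain-type protease, 20.5-fold lower (13.97 to 31.4, 12.6-fold adjusted), the phosphate starvation-responsive gene AT5G03545 16.3-fold lower (13.3 to 20.2) and *BGLU23* 14.9-fold lower (11.7 to 19.2).

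**Figure D3:**
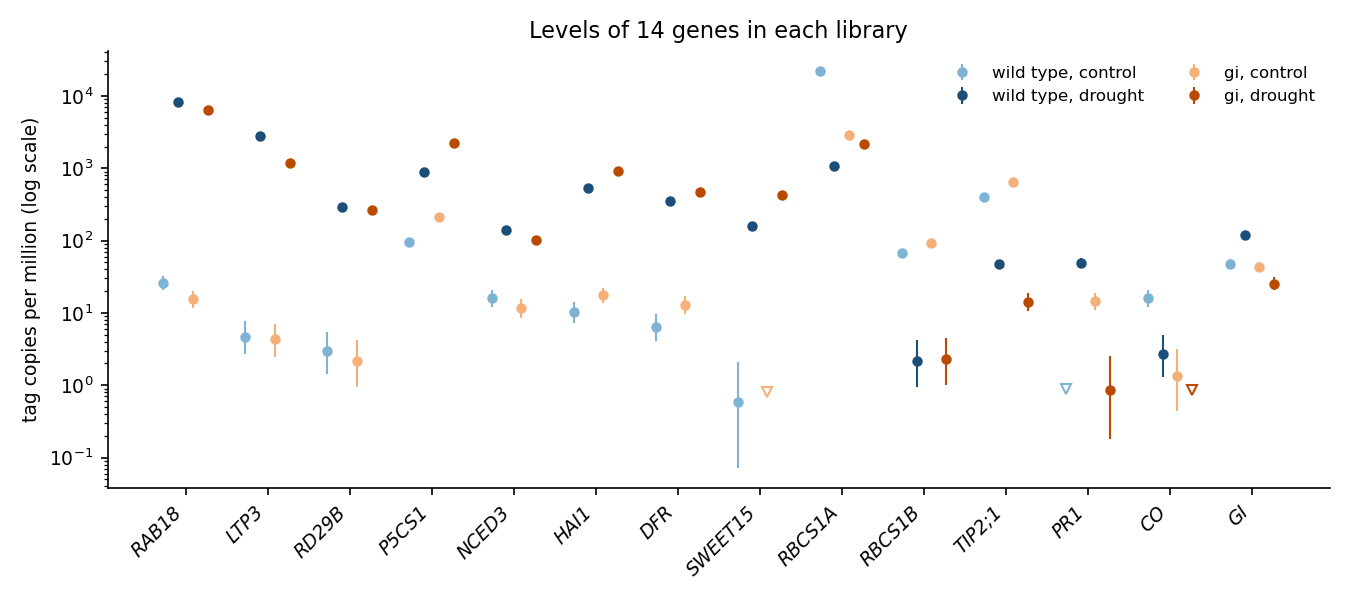
Levels of named genes in the 4 libraries, in TPM on a log axis, with 95% Poisson intervals; open triangles mark genes not listed, drawn at 3 copies. *RAB18* lay at 26.2 and 15.4 TPM in the controls and at 8334 and 6331 after drought.

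The design also allowed the drought responses of the genotypes to be set against each other. Across 6684 genes the log2 drought ratios of the wild type and of *gi* had a Pearson r of 0.0701 and a Spearman rho of 0.0557, and after adjustment 0.629 and 0.534 across 5783 genes. Genes are not independent replicates, so no p-value is attached. Without adjustment 618 genes were higher after drought in both genotypes, against 481 if the calls were independent, 382 were lower in both, against 224, and 690 were called in opposite directions, against 657. After adjustment 657 were higher in both, against 331, 311 were lower in both, against 71.5, and 75 were opposite, against 308. The ratios of *gi* to wild type in control and in drought had an r of -0.477 and a rho of -0.38, and -0.0924 and -0.0662 after adjustment. Each pair of ratios used all 4 libraries.

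**Figure D4:**
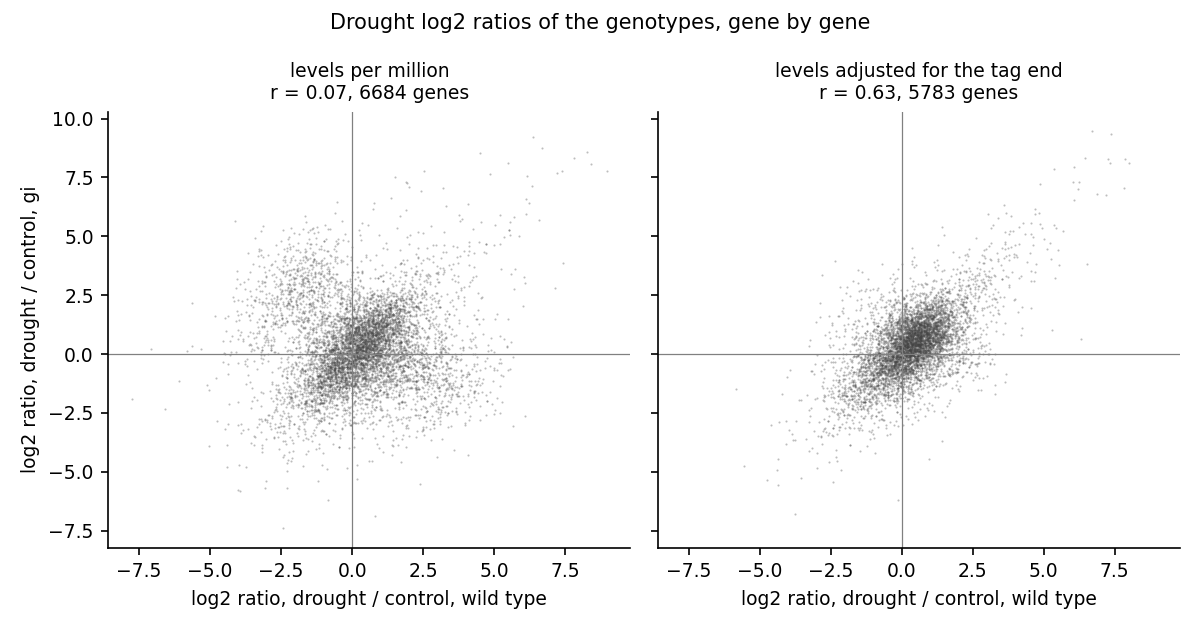
Log2 drought ratio of each gene in *gi* against that in the wild type, without and with the tag-end adjustment. Pearson r was 0.0701 across 6684 genes without it and 0.629 across 5783 genes with it.

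By the rule for differences, a log2 ratio in *gi* at least 1 away from that in the wild type and more than 2 counting standard errors from 0, 1680 genes had a higher and 1853 a lower drought ratio in *gi*. After adjustment these were 943 and 902, of which 622 and 613 were shared. The larger side also turned with TMM factors (1850 higher, 1712 lower), with totals that left out organelle and top genes (1803 and 1725) and at 4-fold (1039 and 1035), but not without tags ending in AA or TT (932 and 1268). The highest differences were 9.76 for AT2G23090 (counting standard error 0.36, 4.75 adjusted), 8.58 for AT3G51500 (0.46, 3.74 adjusted), 8.45 for AT2G35840 (0.38, 4.36 adjusted), 8.35 for *ROC1* (0.16, 3.19 adjusted) and 7.96 for *CIPK21* (0.32, 6.16 adjusted), a kinase of calcium signalling. The main tag of each of these 5 genes ended in TT. The lowest were -8.73 for *PR1* (0.99, -6.20 adjusted, when it no longer reached the minimum level), -8.71 for *WOX12* (0.36, -3.55 adjusted), -8.37 for *SAR1B* (0.46, -4.19 adjusted), -7.91 for *COR15B* (0.23, -5.43 adjusted) and -7.69 for *AAE15* (0.62, -3.23 adjusted), whose main tags ended in AA except for TA in *COR15B*. *COR15B* (AT2G42530, chromosome 2, 17708593 to 17710433) stood at 30.6, 165, 944 and 19.7 TPM in the wild type control, wild type drought, *gi* control and *gi* drought libraries.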

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

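Of the tests below, the search for miscalled tag ends, the count of genes left after the adjustment, both tests on the dehydration-responsive list, and the tests on the adjusted jasmonate and salicylate medians were chosen only after the result they measure had been seen, as was the tag-end adjustment itself. Differences between the genotypes in their drought ratios were not tested, since each group is 1 library.

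The first pattern is that the drought ratios of the genotypes were unlike across genes (Pearson r 0.0701) and that 690 genes were called in opposite directions. Against miscalled bases, copies missing from tags ending in TT in the *gi* control were sought in tags with the same first 19 bases. A median of 0% was found there (69 tags, most of them at 0.327% or less). For the scaling between libraries, the lowest count of genes that differed with TMM or DESeq2 factors was 3562, against 3533 with library totals. That count could hardly have fallen, because a scaling factor shifts the log2 ratios of all genes of a library nearly alike. The differences had a standard deviation of 2.41, far wider than such shifts, so no conclusion on scaling is drawn from the count. A recovery of tags that depended on their last bases may account for much of the first pattern. Between tags of the same gene, which share its expression, differences followed the end factors learnt from 7017 other genes. The r was 0.882 (0.860 to 0.901, 449 genes) and the slope 1.02. With factors learnt on other chromosomes the r between the genotypes went from 0.0122 (2061 genes) to 0.588 (1778 genes), so these factors need not be the whole cause. A genotype effect on the drought response beyond them cannot be told apart from plant-to-plant or batch differences, or from tag-end effects left after adjustment. After it 1845 genes still differed, 115 of them in the direction opposite to their call without it. With 1 library per group there is no spread to set them against.

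The second pattern is that dehydration-responsive genes were higher in both droughted libraries. Against the tag ends as its cause, the list kept 99.5% of its median log2 ratio after adjustment in the wild type, from 3.13 to 3.12, and in *gi* the median went from 2.99 to 3.18. Root, flower and seed markers were used to ask about tissue of another organ, such as seed. Of 24 markers, 8, 8 and 7 can yield an unambiguous tag, and 7, 7 and 2 were listed in any library. Against such tissue, 0 of the 23 reached 30 TPM and 4-fold above control in both droughted libraries. The lower of the droughted levels of each marker counts here, and the highest such value was 20.3 TPM. A marker high in a single droughted library is not covered. The root marker *BGLU23* had log2 drought ratios of 1.57 in the wild type and -2.80 in *gi* without adjustment. A response of leaves to withheld water is the biological explanation that the design names, and it may be the cause, as a hypothesis only, since droughted and control plants may also have differed in age or handling, which the labels leave open.

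The third pattern concerns the *gi* drought library against the wild type drought library. In it 5 of 9 measured jasmonate genes were higher and 3 of 6 salicylate genes lower, and the others neither. These counts were the same with and without adjustment. Among the higher jasmonate genes, however, *AOC2* was counted only without adjustment and *AOS* only with it. Against the tag ends, the jasmonate median was 1.098 after adjustment, at percentile 100 of the random lists, and the salicylate median -1.23, at percentile 0.0400. Touch or wounding before harvest may be a cause and stays open: 10 early touch genes had a median of -0.20 (7 measured members, from -0.76 to 2.101, spread 0.49) at percentile 32.8, inside the range that had been set beforehand as speaking against touch. That range was not a sound bound, because the list left out *RRTF1* and AT4G29780, the high genes that had prompted it (with both the median was 0.04 over 9), and its members went both ways. Loss of *GI* function may be the cause but cannot be told apart from differences between single samples of plants. Between the controls the adjusted salicylate median was higher in *gi*, 0.86 at percentile 99.4 (6 members), and not lower as with drought. Without adjustment it was 0.57 at percentile 88.6 (7 members). No group had a second library.

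Of the genes named in the report, those below drew attention because the drought ratio was at least 2-fold in both genotypes, with intervals that excluded 1, but in opposite directions. Values are the *gi* log2 ratio minus that of the wild type, then the same after adjustment, given whether or not the gene reached the minimum level. *WRKY44*, *SHP1* and *PAD4* did not reach it even without adjustment, and the counting standard errors of their differences were 1.18, 0.94 and 0.60. Where the wild type was lower after drought and *gi* higher, the differences were 9.76 and 4.75 for AT2G23090, 8.58 and 3.74 for AT3G51500, 8.45 and 4.36 for AT2G35840, 8.35 and 3.19 for *ROC1*, 7.96 and 6.16 for *CIPK21*, 7.8 and 3.83 for AT3G06750, 7.58 and 4.45 for *LHCB1.3*, 7.51 and 4.74 for AT4G29780, 7.46 and 4.3 for *STP4*, 7.26 and 2.64 for *ACX2*, and 6.96 and 4.12 for AT5G23460. They were 6.4 and 1.05 for *LHCA2*, 6.13 and 1.3 for *PAO*, 5.94 and 0.71 for *UBQ10*, 5.46 and 1.19 for *SPS4F*, 5.22 and 2.4 for *PIP2;6*, 5.12 and 0.07 for *ACT8*, 5.1 and 0.99 for *GolS1*, 5.05 and 4.16 for *MYC2*, 4.74 and 1.89 for *AOC2*, 4.63 and 2.75 for *WRKY44*, 4.14 and -0.08 for *PRR7*, 3.83 and 3.11 for *SHP1*, and 3.76 and 3.53 for *PGK1*.

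Where the wild type was higher after drought and *gi* lower, the differences were -8.73 and -6.20 for *PR1*, -8.71 and -3.55 for *WOX12*, -8.37 and -4.19 for *SAR1B*, -7.91 and -5.43 for *COR15B*, -7.69 and -3.23 for *AAE15*, -7.67 and -2.99 for *ZFN1*, -7.38 and -2.27 for AT3G28900, -7.35 and -2.52 for *LHCB4.3*, -7.30 and -2.11 for *HSBP*, -6.95 and -4.21 for *ABCB26* and -6.73 and -1.88 for *MKK2*. They were -4.93 and -5.09 for AT1G14240, -4.37 and -2.1 for *BGLU23*, -2.88 and -1.08 for *LHCA1*, -2.86 and 0.41 for *SOC1*, -2.76 and -3.2 for *PAD4* and -2.33 and -1.27 for *BGLU18*. The adjustment thus brought *ACT8*, *PRR7* and *SOC1* to within 0.41 of no difference. A difference that remained need not mean opposite directions. For example, *PAO*, *GolS1* and *UBQ10* were higher in both genotypes after adjustment (log2 0.665, 0.735 and 0.966 in the wild type). *LHCA1* and *LHCA2* were then lower in both (-0.213 for *LHCA1* in the wild type, -0.169 for *LHCA2* in *gi*).

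Signals also appeared in tags outside the gene counts, above their level in the wild type control. Tags that ended in a run of A and matched nothing in the reference made up 3.64% of copies in the wild type drought library, 5.11% in the *gi* control and 0.799% in the *gi* drought library, against 0.0542% in the wild type control. Tags that began with a fixed adapter-like sequence had 11317 copies in the wild type drought library, 27487 in the *gi* control and 5477 in the *gi* drought library, against 2672.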

How the results depend on the processing

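The tag-end adjustment, leaving out tags that end in AA or TT, and setting tags of 2 copies to 0 were chosen after the data had been seen, and the other alternatives before. The 6 summary results are the counts of called genes in the 4 comparisons, the count of genes whose drought ratios differed between the genotypes, and the correlation of those ratios.

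The counts stayed within 1.5 times their values, and the correlation within its interval across genes, under TMM, DESeq2 and upper-quartile scaling, totals without organelle and 20 top genes, both pseudocounts, 1 accepted mismatch, shared tags counted for each gene and tags of 2 copies set to 0. Over these settings the counts were 2949 to 3336 for drought in the wild type, 3011 to 3429 for drought in *gi*, 2358 to 2694 between the controls, 1488 to 1792 between the droughted libraries and 3285 to 3741 for the difference, and r was 0.0599 to 0.0858. The interval of r treats genes as independent, which they are not, so it served only as a rough guide. All 74 list medians stayed within their spread under each of the 4 scalings and a pseudocount of 0.1. In all, 617 of the recomputed list medians stayed within it and 41 did not, most often with a minimum level of 30 (20) and the tag-end adjustment (10). Small medians of *gi* drought lists still changed sign between scalings, as given in the report. Of the recomputed values of named genes, 1242 shifted by no more than a margin set by the width of their interval, 231 moved further and 18 turned direction. For a gene unlisted in a library the interval has no bound, and the margin was set by the size of the log2 ratio itself. That margin is wide for large ratios.

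A lower minimum admits more genes by construction. With no minimum level the counts, in the order above, were 7787, 8085, 7071, 5070 and 7494 and r 0.0237. With 10 TPM they were 5627, 5644, 4721, 3275 and 6123 and r 0.0253. A stricter fold passes fewer: at 4-fold the counts were 1431, 1445, 1351, 400 and 2074, and at 1.5-fold the droughted libraries differed in 2918 genes. With the most 3' site only, r was -0.0183; the cause was not tested.

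With the tag-end adjustment 2051 genes were called for drought in the wild type, 994 between the controls, 706 between the droughted libraries and 1845 for the difference, and r was 0.629, while drought in *gi* gave 2294. Without tags ending in AA or TT the controls differed in 1437 genes, the droughted libraries in 1047 and the difference in 2200, and r was 0.421. Both take away signal tied to tag ends by construction.

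The adjustment also turned the direction of 18 values, given here as adjusted log2 ratios: for drought in the wild type *PRR7* 0.286, *LHCA1* -0.213, *PAO* 0.665, *UBQ10* 0.966 and *GolS1* 0.735; for drought in *gi* *GI* 0.417, *RD29A* 0.721, *SOC1* 0.443, *LHCA2* -0.169 and *ACT8* -0.105; between the controls *RAB18* 0.429, *PRR7* 0.29, *PAL1* -0.794, *TIP1;2* 0.015, *ACT8* 0.043 and *BGLU23* -1.22; and between the droughted libraries *RAB18* 0.517 and *UBQ10* -0.156. Under the scalings and pseudocounts no called gene among those named turned. Why single genes turned was not tested further.

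Leaving out tags seen once was not run, because the lowest copy number in any library is 2. Depth limits what can be called: 3946, 4620, 3901 and 4400 genes reached 30 TPM in the wild type control, wild type drought, *gi* control and *gi* drought libraries, of 18147, 18939, 18572 and 18753 with any copies.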

Other observations

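The genes in this part were chosen after their values had been seen, and none of the comparisons was tested. Some drought calls held in both genotypes with and without the tag-end adjustment: 353 genes were higher and 205 lower after drought each time. These counts used library totals, and adjusted values were not computed with other scalings, on which the split may depend. The adjusted median log2 drought ratio of genes at the minimum level was 0.398 in the wild type and 0.417 in *gi*. Among the genes of these sets not described above, *TSPO*, for a membrane protein of the tryptophan-rich sensory family, was higher by log2 7.21 in the wild type and 7.69 in *gi* (6.44 and 8.34 adjusted), and *LTP4*, for a lipid transfer protein, by 6.16 and 7.57. *PUB19*, of the ARM repeat family, was listed in neither control and had 289 and 486 copies after drought, and *LEA4-5*, a late embryogenesis abundant gene, was likewise unlisted and had 254 and 212. On the lower side were *HBI1*, for a basic helix-loop-helix protein (-5.06 and -3.90, or -4.08 and -3.81 adjusted), *BGAL1*, for a beta galactosidase (-4.42 and -3.86), the carbonic anhydrase gene *CA1* (-3.45 and -3.46, or -3.70 and -2.86 adjusted) and *GASA6*, of the gibberellin-regulated family (-1.73 and -4.75, or -2.97 and -4.84 adjusted).

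Between the genotypes 8 genes were higher and 32 lower in *gi* in both conditions, with and without the adjustment. They are not shown to be a genotype set. Without adjustment 18 genes were higher in both conditions against 125 if the calls were independent, 100 lower against 152 and 725 opposite against 276. With it these were 21 against 16.7, 46 against 31.9 and 111 against 46.1. Higher were *P5CS1*, *LOX3*, for a lipoxygenase (log2 1.55 in control and 2.48 in drought), and the plastid genes *atpA* (1.49 and 1.3), *ndhI* (1.53 and 1.22) and *rpl22* (1.91 and 1.82, or 1.55 and 1.06 adjusted). Lower were *MLP328* (-2.40 and -3.77) and *MLP34* (-2.33 and -2.92), for major latex protein-like proteins, the glycine-rich protein gene *GRP9* (-2.58 and -2.72), the PYK10-binding protein gene *PBP1* (-1.07 and -1.77, or -1.81 and -1.69 adjusted), *IMD1*, for an isopropylmalate dehydrogenase (-1.65 and -1.62), the transporter gene *GTR2* (-1.35 and -1.32) and *RVE2*, a homeodomain-like relative of clock genes (-1.495 and -1.39). *BGLU23*, a root marker also known as PYK10, was lower in *gi* in drought with and without adjustment, and in the control with it only. Plastid-encoded genes as a whole held 0.543% of copies in the wild type control, 0.455% in the wild type drought library, 0.749% in the *gi* control and 0.887% in the *gi* drought library. These shares were not adjusted for tag ends. With oligo(dT) selection and 1 library per group, they cannot tell plastid expression apart from differences in RNA preparation. The same limit holds for *atpA*, *ndhI* and *rpl22*.

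The list of 10 early touch genes had a median log2 ratio of 0.85 in the *gi* control against the wild type control (percentile 93.6, 7 measured members), and 0.62 after adjustment (percentile 95.1, 5 members). Its members went both ways, from -1.35 for *ERF6* to 2.05 for *WRKY40* without adjustment and from -0.53 for *CAF1a* to 1.46 for *TCH3* with it.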
